A study of Homo sapiens with 8 samples.

How the data were processed

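Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase inserts adapters into open DNA, in 8 libraries of 2 human cell lines. Each line had 2 libraries after a non-targeting siRNA (siNTC) and 2 after siRNAs against YAP1 and WWTR1 (siYAP + siTAZ), numbered replicate 2 and replicate 3 in the labels. Libraries were sequenced on a NextSeq instrument, per the labels' protocols. The deposited values are raw counts per peak, 1 table per cell line, whole numbers with a different total in each library. MACS2 and GRCh38 are named in the submitters' processing notes, without version or role. The aligner, read filters, any Tn5 shift, the treatment of mitochondrial reads and the rule that merged peaks are not given in the sources used here, and each of these can change which peaks exist and how reads near their edges were counted.

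The coordinates were checked against chromosome lengths. In Patu-8902 1855 peaks, and in Detroit-562 2235 peaks, ended past the end of their chromosome in GRCh38, and 0 did in GRCh37, so coordinates are given as GRCh37 (hg19). Adjacent peaks were never closer than a gap of 1 and the narrowest peak would span 251 bp, so positions were read as 1-based with both ends included. No genome or gene annotation of GRCh37 was used here and coordinates were not converted. Peaks are therefore named by position and cytogenetic band, with hg19 bands from circlize 0.4.16 and chromosome lengths from GenomeInfoDb 1.38.1. The planned comparisons of promoter and distal peaks, sequence motifs, the YAP/TAZ target list and the other gene lists, the peaks at named genes, and the correction for GC content needed that annotation or sequence and were not run. ATAC-seq does not measure the mRNA that the siRNAs target, so the knockdown itself was not checked.

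Each peak name carries a condition, which includes single knockdowns (siYAP, siTAZ) and, in Detroit-562, siTEADs. The peak sets were thus built over more conditions than the libraries analysed here. How a peak got its condition is not given in the sources used here.

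Each line was tested alone with edgeR 4.0.16 in R 4.3.3, using TMM factors, the filterByExpr filter with its minimum count of 10, the quasi-likelihood F test on treatment and Benjamini-Hochberg adjustment, and peaks with adjusted p under 0.05 were called lower or higher. This kept 109707 of 232434 peaks in Patu-8902 (47.2%) and 186515 of 309011 in Detroit-562 (60.4%). The SE of a log2 fold change is its size divided by the square root of F. CPM are counts scaled by the library's total over the tested peaks (for differences between lines, over the tested matched peaks) and its TMM factor, so they lie above values scaled by all counts, and log2 CPM used a prior count of 2. Peaks of both lines were matched 1 to 1 by overlap of at least 1 bp, each being the other's largest overlap, and the difference between lines was the line by treatment term of 1 edgeR model over all 8 libraries, with TMM factors computed within each line.

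The labels do not say that replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical. With 2 against 2 libraries an exact two-sided permutation test of a single value cannot go below p = 0.333, so single peaks rest on the spread that edgeR pools across peaks. Replicates of a group differed beyond counting noise, with chi-square per degree of freedom of 1.98 and 2.15 in the Patu-8902 controls and treated libraries and 1.70 and 1.79 in those of Detroit-562. Library totals ran from 5807562 to 8666635 counts in Patu-8902 and from 10448892 to 15430422 in Detroit-562. The tests were tried on simulated data with 200 changed peaks. That is far fewer than were called in the data, so the shares recovered do not give the power here. Each simulated peak took the spread typical of its strength, without variation between peaks, so the false calls do not give the error rate here. Of 2-fold and 4-fold changes, 22.4% and 63.6% were recovered among 109707 simulated Patu-8902 peaks, 31.3% and 59.1% among 186515 Detroit-562 peaks, and 4.48% and 45.5% for the difference between lines among 111011 matched peaks, with 1, 0 and 6 false calls.

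Design, tests, alternatives and the rule for named peaks were fixed before the data were examined. The rule took, per line, the 10 called peaks with the most negative and the 10 with the most positive log2 fold change among those with a mean log2 CPM of at least 1 and treated libraries on 1 side of both controls. Its limit of 1 peak per gene was void without gene links. For the lines together it took the 5 matched peaks of smallest p in each direction of the difference, and the 6 called lower in both lines with the smallest larger p. The rule did not say which mean log2 CPM. The mean over the 4 libraries was used, and that reading was settled after exploratory fits had been seen. With edgeR's average log2 CPM, 0 of the 10 lower peaks would have been the same in either line, and those lists are summarised with the named peaks. Stitched regions held at least 5 peaks at most 12500 bp apart, with counts summed. Candidates for naming had a sum called in the direction (adjusted p under 0.05) and 0 opposite peak calls. The 6 with the most calls were named per direction. These regions, bands with at least 100 tested peaks, chromosomes, neighbouring peaks within 10000 bp with 1000 permutations of the calls within 10 classes of strength, peak strength in 5 classes, peak names and the alternatives for calls shared by both lines were all chosen after the data were seen. Alternatives changed the scaling, the low-count filter, the tool, the adjusted p threshold, the replicate block, the overlap of matched peaks and the libraries included, with DESeq2 1.42.0 and limma 3.58.1. Each fit of peaks with a library left out also reran the low-count filter. Folds of peaks with 0 counts in a group are also given at a floor of 3 counts over that group. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.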

Results

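ATAC-seq counts were compared between siNTC and siYAP + siTAZ in Patu-8902, a pancreatic ductal adenocarcinoma line, and Detroit-562, a pharyngeal carcinoma line. YAP1 and WWTR1 (TAZ) are transcriptional co-activators held in check by the Hippo pathway, and they act on DNA mainly through TEAD proteins. The series title places the lines in a study of dependency on this pathway, and the comparison asks where accessibility changed when both co-activators were targeted. Each group held 2 libraries. In Patu-8902 the controls had 8666635 and 7592679 counts in peaks and the treated libraries 7827870 and 5807562. In Detroit-562 the controls had 15428531 and 15430422 and the treated libraries 10572403 and 10448892, so the treated libraries were the shallower ones in that line. Across tested peaks, log2 CPM of replicates correlated at 0.920 to 0.939 in Patu-8902 and 0.926 to 0.951 in Detroit-562, against 0.832 to 0.846 and 0.831 to 0.837 between groups. These correlations run across peaks, which are not independent replicates.

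In Patu-8902, of 5353 stretches of at least 5 neighbouring peaks 1083 were lower and 1390 higher in summed counts, while single peaks were more often lower. Summed counts weigh strong peaks most. Strong peaks leaned higher, a trend that could not be told apart from a difference in background between libraries. Of the 1234 stretches with at least 3 called peaks, 776 had calls in 1 direction. The stretches named here were taken from those with 0 opposite calls and a called sum. The direction of their sums was thus set by the naming. On 5q34 (chromosome 5, 167684921 to 167810430), 18 of 33 peaks were called lower and 0 higher, 30 had a fitted change below 0, and the summed signal went from 565 ± 9.68 CPM in controls to 281 ± 0.0866 CPM in treated libraries (SD, n = 2). On 3q22.2 (chromosome 3, 134045789 to 134101403), 13 of 20 peaks were called lower, and the sum changed by -1.04 ± 0.07 on the log2 scale (SE). Further losses covered 18q11.2 (chromosome 18, 21402663 to 21466033, log2 fold change -1.10), 14q11.2 (chromosome 14, 21074510 to 21109650, -0.81) and 7p11.2 (chromosome 7, 55111482 to 55154858, -0.75). Of the 6 named stretches that rose, 4 lay on chromosome 19. On 19p13.2 (chromosome 19, 7894570 to 7937248), 10 of 15 peaks were called higher and the sum went from 296 ± 1.01 to 516 ± 12.0 CPM. On 19p13.3 (chromosome 19, 1155070 to 1296211) 14 of 57 peaks were called higher and 10 had a fitted change below 0, with a log2 fold change of 0.59 ± 0.07 for the sum.

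Over all 109707 tested peaks of Patu-8902, 11920 (10.9%) were lower and 7022 (6.40%) higher after siYAP + siTAZ by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The median log2 fold change was -1.63 among lower peaks and 0.81 among higher peaks, and 10001 lower peaks against 2639 higher peaks changed by over 2-fold. Among these, 67 lower peaks had 0 treated counts and 6 higher peaks 0 control counts, too few to move a median. With them at a floor of 3 counts over the group the medians were -1.63 and 0.81. Weak peaks need a larger fold than strong ones to be called. The strongest of 5 classes held 3837 of the higher but 1799 of the lower peaks. The fold sizes thus do not compare losses with gains at equal strength. Fits with a library left out reran the low-count filter and tested 125011 to 135972 peaks. Without siNTC replicate 2 the calls were 7272 lower and 2622 higher, without siNTC replicate 3 they were 6580 and 2020, and without siYAP + siTAZ replicate 2 they were 9715 and 4633. DESeq2 called 5006 lower and 2387 higher, and limma-voom called 3891 and 3504 without siYAP + siTAZ replicate 2 and turned the balance without siYAP + siTAZ replicate 3, with 5195 lower and 5678 higher.

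Among the named Patu-8902 peaks, a peak on 9q31.3 (chromosome 9, 114804088 to 114804379) went from 27.2 ± 1.61 to 0.954 ± 0.565 CPM (SD, n = 2), a log2 fold change of -4.90 ± 0.32 (SE, adjusted p = 1.31e-10, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). A peak on 8q24.21 (chromosome 8, 130489763 to 130490038) went from 14.2 ± 1.19 to 0.429 ± 0.214 CPM, and one on 5q23.1 (chromosome 5, 119940634 to 119940906) from 19.1 ± 0.625 to 0.692 ± 0.390 CPM. Among the named gains, a peak on 4p15.32 (chromosome 4, 16125034 to 16125443) went from 1.41 ± 0.212 to 31.7 ± 1.35 CPM, a log2 fold change of 4.46 ± 0.26. A second named peak lay within the same band (16124644 to 16124918) and rose by 3.64 on the log2 scale. A peak on 5q32 (chromosome 5, 149012326 to 149012624) rose by 3.67 ± 0.31 on the log2 scale (SE). Of the 26 peaks named in this line, 11 lost their call in at least 1 limma-voom fit with a library left out, with adjusted p up to 0.421, among them the 8q24.21 peak and the second 4p15.32 peak. Under the other reading of mean log2 CPM, the 10 lower peaks would all have had 0 counts in both treated libraries and 51 to 127 in the controls. The first of them, on 20p12.1 (chromosome 20, 12376125 to 12376486), was at least 34.0-fold lower against a floor of 3 counts over the treated group, which covers counting error only. Of the 10 higher peaks 6 would have been the same, and the others lay on 7q22.1, 2q22.3, 4p15.33 and 10p13.

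**Figure D1:**
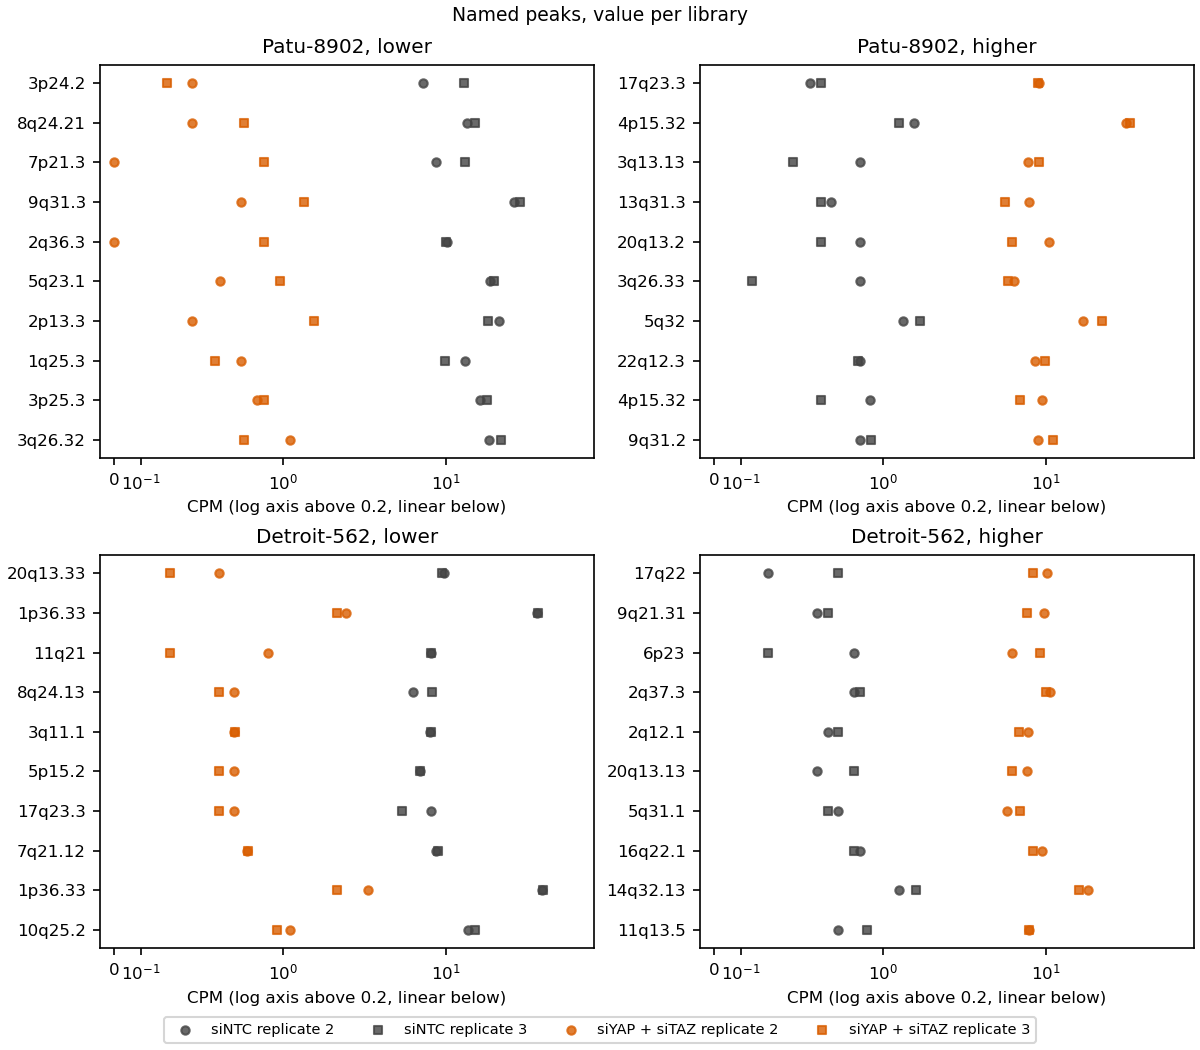
CPM of the named peaks in each library, by cytogenetic band, with circles for replicate 2, squares for replicate 3, dark grey for siNTC and orange for siYAP + siTAZ; the axis is logarithmic above 0.2 and linear below. In each peak both treated libraries lie on 1 side of both controls, as the naming rule required, and the 9q31.3 peak of Patu-8902 lies near 27.2 CPM in controls and 0.954 in treated libraries on average.

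In Detroit-562, of 11407 stretches 1968 were lower and 3304 higher in summed counts. Here too single peaks were more often lower, and the sums weigh strong peaks most. Of the 2865 stretches with at least 3 called peaks 1222 had calls in 1 direction. Named by the same rule, 5q35.3 (chromosome 5, 180542108 to 180674148) had 20 of 46 peaks called lower and 0 called higher, 41 had a fitted change below 0, and the sum went from 504 ± 9.12 to 338 ± 8.59 CPM (SD, n = 2). Losses of about 2-fold covered 6p22.1 (chromosome 6, 27506192 to 27603961, log2 fold change -1.03) and 14q22.2 (chromosome 14, 55091649 to 55176909, -0.94). Gains were marked on 7q22.3 (chromosome 7, 105879855 to 105911281), where 14 of 17 peaks were called higher and the sum went from 37.7 ± 2.88 to 100.6 ± 13.9 CPM. On 11p15.5 (chromosome 11, 1241030 to 1285954) 14 of 18 peaks were called higher, and the sum went from 54.9 ± 1.46 to 112 ± 19.6 CPM. On 20q13.13 (chromosome 20, 48828107 to 48963522) 16 of 35 were called higher, with a log2 fold change of 0.77 ± 0.05 for the sum.

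**Figure D2:**
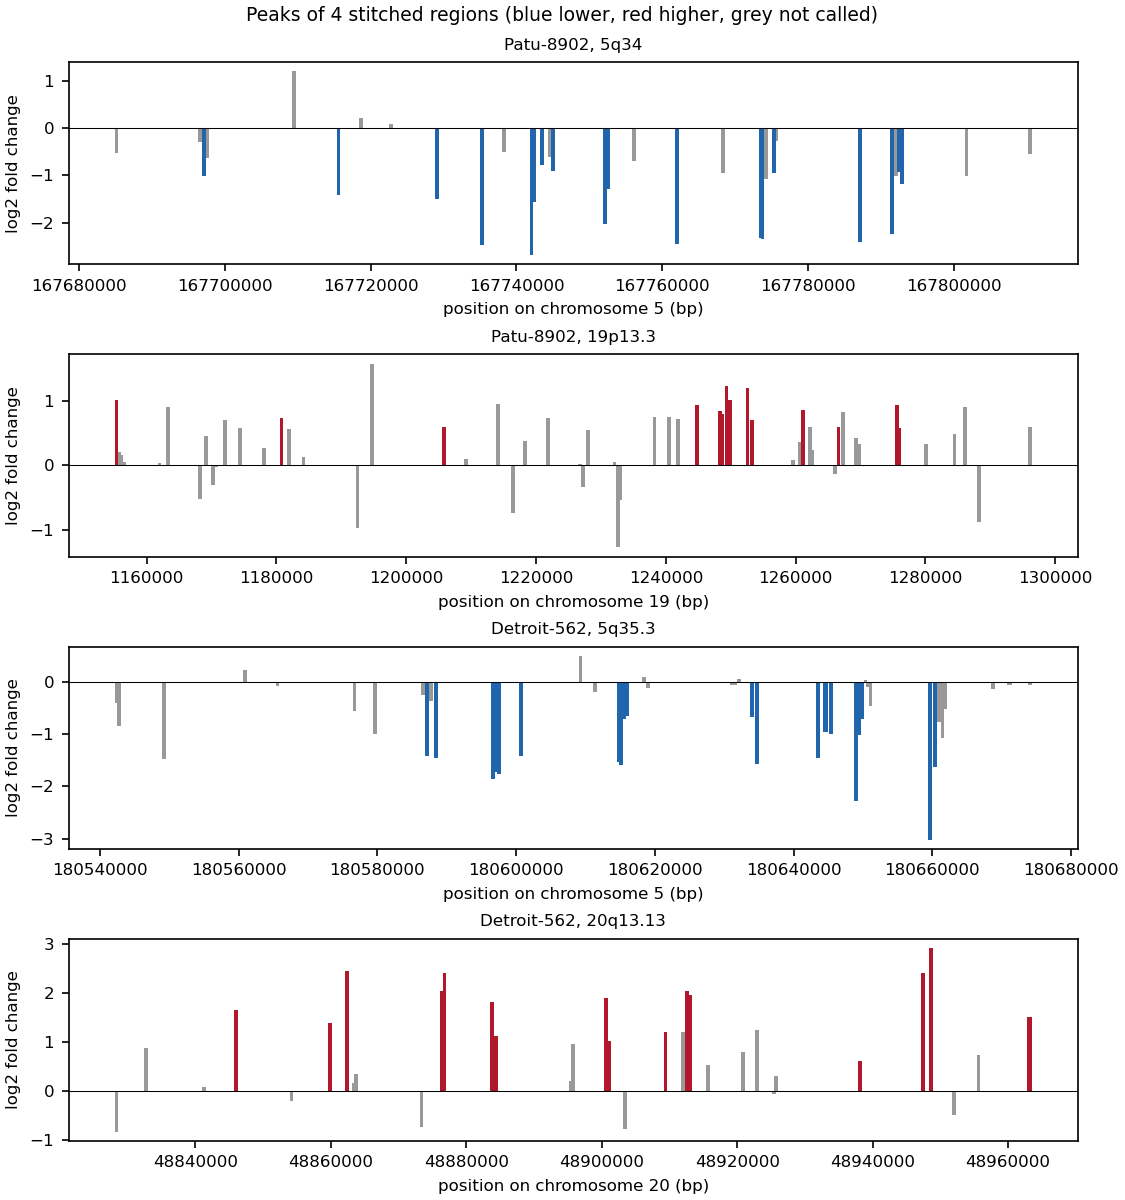
Log2 fold change of each tested peak, siYAP + siTAZ over siNTC, against position in the stitched region with the most lower and the most higher peaks in each line; blue bars were called lower, red bars higher, and grey bars were not called, and narrow peaks are drawn wider than they are. In 5q34 of Patu-8902 18 of 33 peaks are blue, and in 20q13.13 of Detroit-562 16 of 35 are red.

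Over all 186515 tested peaks of Detroit-562, 20005 (10.7%) were lower and 16852 (9.04%) higher by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The median log2 fold change was -1.65 among lower peaks and 1.03 among higher peaks, and 16312 lower against 8769 higher peaks changed by over 2-fold. Among these, 237 lower peaks had 0 treated counts and 1 higher peak 0 control counts, too few to move a median. With them at the floor the medians were -1.65 and 1.03. Here too the strongest of 5 classes held 7209 of the higher but 2694 of the lower peaks. The fold sizes of called peaks thus do not compare losses with gains at equal strength. Without siNTC replicate 2, siNTC replicate 3, siYAP + siTAZ replicate 2 or siYAP + siTAZ replicate 3, edgeR called 0 peaks, and limma-voom also called 0, while 33065, 33039, 45020 and 47367 peaks had an unadjusted p under 0.05 in edgeR against 61337 with all libraries. The fits with a library left out reran the low-count filter and tested 189352 to 229826 peaks, against 186515 with all libraries. The effect of that wider peak set was not separated from the loss of a library. With all 4 libraries limma-voom turned the balance, with 13750 lower and 16591 higher. EdgeR without a low-count filter called 8558 and 6894, and DESeq2 called 11181 and 9931.

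Among the named Detroit-562 peaks, one on 20q13.33 (chromosome 20, 58956936 to 58957346) went from 9.56 ± 0.103 to 0.305 ± 0.143 CPM (SD, n = 2), a log2 fold change of -4.92 ± 0.36 (SE, adjusted p = 3.88e-06, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). A peak on 10q25.2 (chromosome 10, 112971494 to 112971810) went from 14.4 ± 0.973 to 1.02 ± 0.140 CPM. A pair of named peaks on 1p36.33 (chromosome 1, 567445 to 567708 and 569793 to 570051) fell by 3.97 and 3.82 on the log2 scale, and the first of the Patu-8902 peaks that overlap them had 368 and 52 counts in the treated replicates. The named gains included 17q22 (chromosome 17, 57459089 to 57459420, from 0.365 ± 0.234 to 9.20 ± 1.33 CPM), 14q32.13 (chromosome 14, 94856873 to 94857219, from 1.43 ± 0.233 to 17.0 ± 1.58 CPM) and 2q37.3 (chromosome 2, 237895196 to 237895567, from 0.697 ± 0.046 to 10.3 ± 0.389 CPM). All 26 Detroit-562 peaks that the rule named lost their call when any 1 library was left out. Under the other reading of mean log2 CPM the lower list would have begun with a peak on 6p22.1 (chromosome 6, 27543763 to 27544108), with 98 counts in controls and 0 in treated libraries, at least 21.3-fold lower against the floor of 3 counts. The other lower peaks of that list had 1 to 3 treated counts and 95 to 198 control counts. Of its 10 higher peaks 7 were the same, and the others lay on 3q13.32, 10p13 and 3q26.32.

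**Figure D3:**
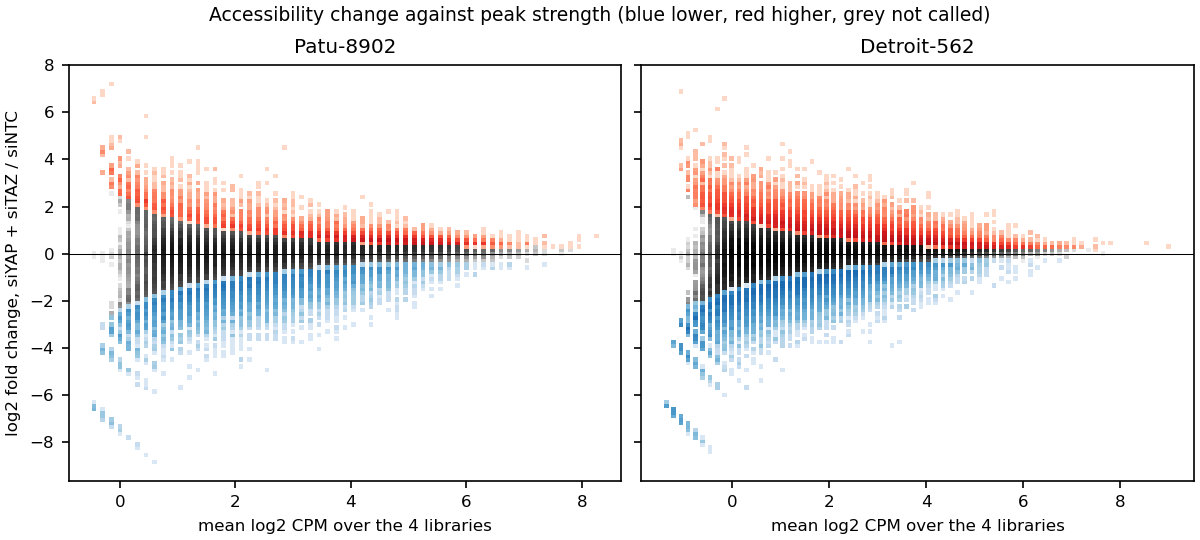
Log2 fold change, siYAP + siTAZ over siNTC, against mean log2 CPM over the 4 libraries of each line, in bins coloured blue (called lower), red (called higher) or grey (not called), darker with more peaks on a log scale. Median log2 fold change goes from -0.20 in the weakest of 5 classes to 0.18 in the strongest in Patu-8902 and from -0.34 to 0.15 in Detroit-562; the separate arms below -6 are the 67 and 237 peaks with 0 treated counts, whose fitted folds depend on the prior count.

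Some peaks changed in the same direction in both lines. A peak on 11q14.3 (chromosome 11, 92002279 to 92002557 in Patu-8902) fell by 4.12 in Patu-8902 and by 2.43 in Detroit-562 on the log2 scale. Further peaks called lower in both lines lay on 2q36.3 (chromosome 2, 227342808 to 227343380, log2 fold changes -3.32 and -2.12), 3q12.2 (chromosome 3, 100755179 to 100755452, -2.82 and -1.66) and 1p22.3 (chromosome 1, 86072899 to 86073180, -2.62 and -2.25). Among 81504 matched peaks tested in both lines, 2923 were lower in both where independent lists would share 665, and 1649 were higher in both against 585. Opposite calls were fewer than independent lists would share. They numbered 482 against 909 for lower in Patu-8902 and higher in Detroit-562, and 65 against 428 for the reverse. These expected counts ignore that neighbouring peaks share calls and that calls vary with peak strength. In the strongest of 5 classes, 17.5% of Patu-8902 and 19.3% of Detroit-562 tested peaks were higher, against 6.40% and 9.04% over all tested peaks. Across the matched peaks, which are not independent replicates, log2 fold changes correlated at r = 0.390 and rho = 0.310. Without any 1 Detroit-562 library (siNTC replicate 2 or 3, siYAP + siTAZ replicate 2 or 3) edgeR called 0 peaks in that line with 1 residual degree of freedom, so 0 calls were shared. Without Patu-8902 siNTC replicate 2 the shared calls were 2078 lower and 781 higher, without its siNTC replicate 3 1943 and 649, and without its siYAP + siTAZ replicate 2 2409 and 1025. DESeq2 gave 1220 lower and 577 higher in both lines, edgeR without a filter 1799 and 613, and loess offsets 2916 and 994.

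**Figure D4:**
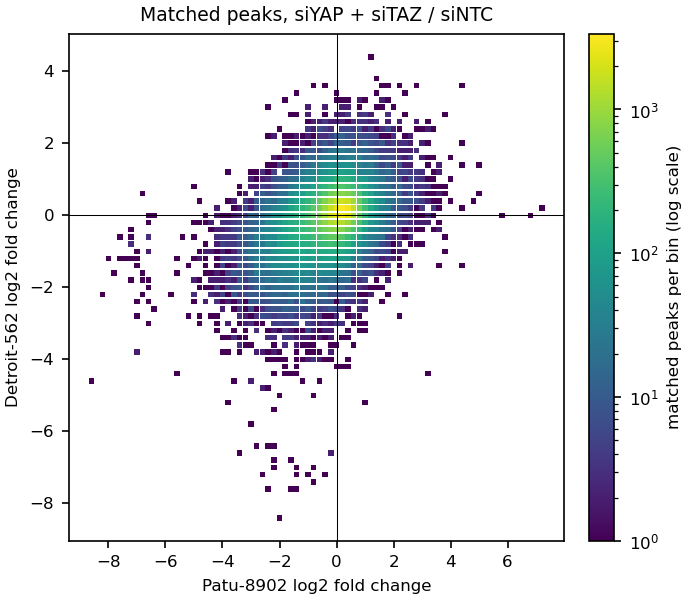
Log2 fold change after siYAP + siTAZ in Detroit-562 against Patu-8902 for matched peaks tested in both lines, coloured by the number of peaks per bin on a log scale. The cloud tilts upward, with r = 0.390 over 81504 peaks.

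Other matched peaks changed differently in each line. The test of the difference itself called 8009 of 111011 matched peaks by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of these, 5420 had the Detroit-562 change above that of Patu-8902 and 2589 below. Its low-count filter asked for enough counts in 2 of the 8 libraries, and 81504 matched peaks passed the filter of both lines' own fits. Some differences may thus set a response against a line near its floor. On 4p15.32 the peak that rose in Patu-8902 overlapped one that stood at 37.6 ± 2.37 CPM of matched-peak counts in Detroit-562 controls and at 44.3 ± 0.240 after treatment (SD, n = 2). On 3q22.2 (chromosome 3, 134069771 to 134070052) the peak went from 59.1 ± 7.85 to 7.18 ± 2.23 CPM in Patu-8902 and from 58.0 ± 1.47 to 53.2 ± 1.65 CPM in Detroit-562. On 3q27.3 (chromosome 3, 186904665 to 186905223) it went from 23.9 ± 1.51 to 3.63 ± 0.338 CPM in Patu-8902 and from 8.50 ± 1.97 to 19.0 ± 1.88 CPM in Detroit-562. The count fell to 4579 without Detroit-562 siNTC replicate 2 and to 4934 without Detroit-562 siNTC replicate 3.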

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

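These results stand out because the response differed between the lines by a test of the difference. That test was planned, and the test of a local response on 1p36.33 was chosen after its result had been seen. In all, 8009 matched peaks differed. The log2 fold change of Detroit-562 minus that of Patu-8902 was -4.22 on 4p15.32, -3.83 on 5q32, -3.32 on 6p12.1, -2.05 on 17q21.31 and -4.54 on 14q32.2. It was 2.95 on 3q22.2, 2.67 on 11q14.1, 3.88 on 3q27.3, 3.29 on 3q27.1 and 1.88 on 11q13.3. The fitted changes had opposite signs in 8 of these 10 peaks, for example 1.85 in Patu-8902 and -1.48 in Detroit-562 on 6p12.1. Of those 8, 5q32 and 11q13.3 had Detroit-562 changes of only -0.18 and 0.12, so their signs say little. The signs were the same on 4p15.32 and 3q22.2. Of the 8009 peaks, 5453 (68.1%) had fitted changes of opposite sign, and in 547 both changes were called in their own line. Choosing peaks by a large difference itself favours opposite signs, and the share over all matched peaks was not computed. The filter of this test did not require counts in both lines, so some signs may come from a line near its floor. No explanation of these differences was tested, and the lines differ in tissue of origin.

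A named peak on 1p36.33 fell in Detroit-562 from 36.0 ± 0.342 to 2.29 ± 0.206 CPM at 567445 to 567708 of chromosome 1, and a candidate explanation is that mitochondrial reads were placed on nuclear copies of mitochondrial DNA there. This hypothesis came from Patu-8902, where most peaks on 5q31.1 (chromosome 5, up to 134262900 in Detroit-562) were low in 1 treated replicate together with those on 1p36.33, and it required the 5q31.1 peaks to fall in Detroit-562, a value not yet seen when the bound of -2 was set. Their median log2 fold change there was -2.67, and 1 of the 5 peaks (134252830 to 134253101) changed by -0.30. A local response shared by the lines would need both treated Patu-8902 libraries below both controls, and the peaks overlapping the named pair had 368 and 382 counts in treated replicate 2, between controls of 313 and 511 and of 337 and 575, and 52 and 63 in replicate 3. Over all 3 Patu-8902 peaks of the place, the smallest difference between treated replicates lay at percentile 97.8 of peaks at least as strong. That was short of the bound of 99 for excluding a local response, a bound set after the result had been seen. These Patu-8902 values do not bear on a response in Detroit-562 alone, which stays open.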

How the results depend on the processing

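Settings with peaks named for other knockdowns, thinning to equal depth and limma-voom with a library left out were chosen after the data were seen, as were all settings for stitched regions and for calls shared by both lines. DESeq2 gave 5006 lower and 2387 higher peaks in Patu-8902, 11181 and 9931 in Detroit-562, and 1220 lower and 577 higher in both lines, and the cause was not tested. At adjusted p under 0.01 Patu-8902 had 7130 and 2845 and Detroit-562 9578 and 7588, by the stricter threshold itself. Peaks named for other knockdowns alone gave 2049 and 403 in Patu-8902 and 4853 and 4491 in Detroit-562. This left out the peaks named for siNTC, which held 9295 of the 11920 and 15365 of the 20005 lower peaks, and those named for siYAP + siTAZ, which held 6181 of the 7022 and 7920 of the 16852 higher peaks. It also refitted scaling and spread on the peaks left, and in the fits of all peaks those named for siTAZ in Patu-8902 alone held 455 higher calls and those named for siTEADs in Detroit-562 alone 6162, so gains were lost among the peaks left too, and the cause was not tested. With no filter Detroit-562 had 8558 and 6894, with 1799 lower and 613 higher in both lines, and edgeR's prior degrees of freedom in that line went from 11.8 to 4.89. Loess offsets gave 994 higher in both lines, and the cause was not tested.

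With 1 library left out, the lone library of a group is assumed to vary like the others. Patu-8902 then had 6580 to 10985 lower and 2020 to 6380 higher by edgeR. By limma-voom it had 6880 and 2214 without siNTC replicate 2, 7434 and 2763 without siNTC replicate 3, 3891 and 3504 without siYAP + siTAZ replicate 2, and 5195 and 5678 without siYAP + siTAZ replicate 3, where gains came to outnumber losses, and 11 of 26 named peaks lost their call in 20 of 104 comparisons. Detroit-562 had 0 of each by both tools, with 1 residual degree of freedom, edgeR prior degrees of freedom of 1.28 to 1.83, and a smallest adjusted p of 0.217 to 0.284 by edgeR. In Patu-8902, with the same residual degree of freedom, the edgeR prior degrees of freedom were 31.0 without siNTC replicate 3 and infinite without each other library, so the Detroit-562 tests rested on fewer degrees of freedom in all. The difference between lines gave 4579 to 7264, and shared calls 0 to 2783 lower and 0 to 1487 higher.

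The replicate numbers were not shown to pair libraries, since deviations of same-numbered libraries correlated at 0.085 in Patu-8902 and 0.002 in Detroit-562. A replicate block gave 13684 lower and 9698 higher in Patu-8902, 22619 and 19517 in Detroit-562, and 7776 for the difference between lines. With all libraries limma-voom gave 13750 lower and 16591 higher in Detroit-562, a lower share of 45.3%, and the cause was not tested. Scaling by library size alone moved the lower share of calls from 62.9% to 68.1% in Patu-8902 and from 54.3% to 62.2% in Detroit-562. No named peak, region or difference reversed under the settings run. The named regions (12 in each line) and 10 differences between lines kept their call in the settings run for them. A call in the main fit had been a condition of naming both. Those were all edgeR fits, and DESeq2 and limma-voom were not run on regions or differences. GC offsets, alone or with the block, and all alternatives for promoters, motifs and gene lists were not run. In data simulated at these depths 22.4% of 2-fold changes were recovered in Patu-8902 and 31.3% in Detroit-562.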

Other observations

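The tests of explanations that follow were in part chosen after the patterns had been seen, namely those on peak strength. All measurements by chromosome, band and neighbour were chosen after the data were seen. Chromosome 19 of Patu-8902 had 18.4% of its 4226 tested peaks higher and 3.38% lower, and chromosomes 17 and 22 had 12.1% and 11.4% higher. In Detroit-562 chromosome 19 had 8.30% higher and 3.50% lower, and chromosome 11 had 12.2% higher. In bands of the darkest stain class 14.4% of Patu-8902 peaks and 14.7% of Detroit-562 peaks were lower, against 10.0% and 9.63% in unstained bands. The lightest stained class lay below unstained bands, with 8.34% and 9.13% lower. The band 1p21.3 had 30.0% of its tested peaks lower in Patu-8902, and 11q22.2 had 27.5% higher in Detroit-562. Over 428 bands the share of lower peaks correlated between the lines at r = 0.593 and rho = 0.621 (one-sided permutation p = 1e-05 for each, the smallest that 100000 permutations can give). Without the 2 bands farthest from the median share in Patu-8902 it correlated at r = 0.604. Bands extreme in Detroit-562 alone were not left out. The share of higher peaks correlated at r = 0.193 (one-sided permutation p = 8e-05) and rho = 0.274 (one-sided permutation p = 1e-05), and at r = 0.210 without 2 bands chosen likewise by Patu-8902. Neighbouring bands are not independent, and GC content was not tested as a cause of these patterns by chromosome and band.

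Calls of 1 direction lay side by side. Of lower peaks with a tested neighbour within 10000 bp, 34.7% in Patu-8902 and 27.7% in Detroit-562 had a lower neighbour, against 10.8% and 10.6% after permuting calls. For higher peaks the shares were 26.3% and 24.6% against 9.08% and 11.3% (one-sided permutation p = 0.001 in each of the 4 comparisons, the smallest that 1000 permutations can give). The condition in a peak's name went with its change. Of peaks named for siNTC, 17.8% were lower and 0.410% higher in Patu-8902, and of those named for siYAP + siTAZ 0.124% were lower and 26.4% higher. Names came from the study's own peaks, so they are not independent evidence of direction.

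Weak peaks leaned lower and strong peaks higher in both lines, with a difference between the strongest and weakest of 5 classes of 0.38 in Patu-8902 and 0.49 in Detroit-562 on the log2 scale. Among peaks named for another knockdown the difference was 0.214 ± 0.036 and 0.334 ± 0.0058 (jackknife SE over chromosomes). The trend was thus not confined to peaks named for siNTC or siYAP + siTAZ. Peaks named for another knockdown were still sorted by condition, so this cannot exclude selection. In Detroit-562, 8.35% of peaks named for siTAZ were lower and 2.71% higher, against 3.66% and 9.11% of those named for siTEADs. A difference in background between libraries cannot be told apart from a response, because only 2 libraries stand for each group. The largest such difference between replicates of a group was 0.192 in Patu-8902 and 0.0163 in Detroit-562. GC content was not tested.

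The correlation of fold changes between lines was weighed against the same trend and selection, in tests set before their values were seen. Within 5 classes of strength the lowest correlation was 0.329 ± 0.015 (jackknife SE), which argues against peak strength as the whole cause. Among 14362 matched peaks named for another knockdown in both lines the correlation was 0.254 ± 0.010. That was lower than over all matched peaks and above the bound of 0.2 set beforehand. The correlation was thus not confined to peaks named for siNTC or siYAP + siTAZ. Those 14362 peaks were still sorted by condition, so selection stays open. A response to the knockdown that both lines share is a hypothesis for this correlation, and it was not separated from selection of peaks. Controls also received an siRNA, and effects of the treated siRNAs beyond YAP1 and WWTR1 were not tested. GC content, which could act alike in both lines, was not tested either.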
